A study of Mus musculus with 6 samples.

How the data were processed

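The values are RNA sequencing counts per gene in 6 mouse libraries, 3 control and 3 spinal cord injury, with the group taken from the sample group field of the labels and the replicate number from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and made into libraries with an Illumina TruSeq kit. The submitters' processing notes name Bowtie 0.12.2 and the mouse builds mm8 and mm9. Per the file headers, the authors made the deposited counts with featureCounts 2.0.1 on read pairs with both ends mapped, leaving out pairs that map to different chromosomes, summed over exons by gene name, without strand and without multi-mapping or overlapping reads. So reads of a gene and of an antisense or overlapping gene cannot be told apart, and near-identical copies lose reads. All 6 headers name 1 run folder. The aligner behind these counts, the genome build of the reads and the annotation release are not given in the file headers. A table of the whole series repeats the same counts, with 0 cells differing, and its deposited columns named FPKM were not used for any test.

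The start and end that the files give for each exon were set against GENCODE M21 on GRCm38, without converting any coordinate. A feature was called name-stable when at least 90% of its exonic bases lay on exons of the gene of the same name, or of a name that a single RefSeq gene record holds for it as a synonym (Gata6os in this way). A feature was given an overlying gene when it shared at least 100 bases with exons of the annotation and 1 gene held at least 90% of the shared bases. 12320 features had one and held 44.4% of all counts. The overlay was tested on 3000 genes: with no shift 100% were name-stable, and after a shift of 50 kb 0%. Coordinates in the text are those of the files, whose build is not named, and the exons of a name-stable gene overlap its GRCm38 exons by at least 90%, with small offsets in some.

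The main test was edgeR 4.0.16 (R 4.3.3): counts as deposited, TMM scaling, default filterByExpr, quasi-likelihood F test of injury against control over all 6 libraries with no covariate, and Benjamini-Hochberg adjustment with calls at 0.05. CPM values are counts divided by the library's total count and multiplied by 1000000. Gene lists (44, fixed in advance) were tested with camera (two-sided, limma 3.58.1, preset correlation of 0.01, at least 3 tested members, adjusted over lists), with an estimated correlation as an alternative and with fry beside it. Principal components used log2 CPM with a prior count of 2 over the 500 most variable tested features. Standard errors of log2 fold changes were taken from the F statistic.

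The rule for named genes was fixed before the data were examined: the 12 largest rises and 12 largest falls past the threshold with at least 5 mean CPM in the higher group, groups that do not overlap and no predicted gene models or pseudogenes. With none past it, the rule takes the 5 smallest unadjusted p per direction. It adds up to 4 members of each list, of which the text names only some because most list members are not name-stable, and 18 genes set in advance. After seeing the data, the same rule was applied to name-stable genes in the fit without control 3. Without controls 1 and 2, 2 name-stable genes that passed both over all features and alone are named. Members of lists read by overlying gene were picked after their values were seen. Some genes that the rule takes are not reported here. The code of the ribosomal protein test first asked for at least 3 features on their own exons, a condition the written prediction lacked. It was dropped after the value was seen, so the result rests on 2 such features. Shares of counts carry 95% Wilson intervals.

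Alternatives planned in advance were RLE, upper quartile and total count scaling, no filter beyond 1 count, a filter of 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom with and without sample quality weights, the replicate number as a block, stricter thresholds, removal of haemoglobin, mitochondrial and the 10 most abundant features, and leaving out each library. Added after seeing the data were the fit without controls 1 and 2, the fits on name-stable genes (library sizes from all features), and the fits by overlying gene. The pipeline was tested on simulated counts with 200 changed genes, 50 at each fold. With the spread of all 6 libraries over 12646 features it recovered 0% of genes changed 16-fold. A further simulation of 6 libraries gave every gene the common dispersion of the fit without control 3, not its own as in the others. There the pipeline recovered 92% at 4-fold and 100% at 8-fold, which cannot be set against the other shares. For the fit without control 3 (15320 features) it recovered 50% at 4-fold and 100% at 16-fold, and for the fit without controls 1 and 2 (13857 features) 62% at 2-fold and 100% at 4-fold. Total counts of 2385703 to 3921627 per library limit what can be seen of low genes, and intervals and floors cover counting error only.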

Results

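RNA sequencing counts were analysed for 6 mouse libraries of strain C57BL/6, 3 labelled control and 3 labelled spinal cord injury. The labels name the tissue both as spinal cord and as the disc between vertebrae, the series text also names retina, and no time after injury is given. Total counts were 3896310, 3921627 and 2615213 in controls 1, 2 and 3, and 2905828, 2847578 and 2385703 in injury 1, 2 and 3. Nothing in the labels says that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. No pair of libraries agreed within sampling noise (chi-square per feature of 3.55 or more), so all 6 were kept as separate samples.

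A gene name in the counts did not always stand for counts on that gene. The files give a start and end for each of 53546 gene features, and these were set against the exons of the GENCODE M21 annotation, which is on the mouse build GRCm38. 1755 features (3.28%) lay with at least 90% of their exonic bases on exons of the same gene and are called name-stable here. 16030 features (29.9%) shared bases with exons of other genes and none with exons of the gene of their name, and held 69.9% of all counts. Such a feature is said to lie on exons of other genes, though part of it may lie off exons. A feature is said to lie in introns when it shared no base with exons but lay at least partly within a gene. In control 1, 21.8% of the counts (95% Wilson interval 21.75% to 21.83%, counting error only) fell on the feature named Ltbp3, which lies on exons of Malat1, and in control 2 17.2% (17.17% to 17.25%). All 37 mitochondrial features had 0 counts in all 6 libraries. Values below are therefore given by name for name-stable genes. Where the name does not hold, the feature's position is given. A gene it is said to fall on shares the most exonic bases with it of all other genes. That gene does not meet the rule for an overlying gene for the features named Cnfn, D830036C21Rik, Atp1b3, Il1b and Col2a1. Values are also given by overlying gene, summing features with at least 100 bases on exons and at least 90% of those on 1 gene. The rest of such a feature may lie off exons and parts of the gene may go uncounted, so these values are not the gene's full level. The reading by overlying gene and the restriction to name-stable genes were chosen after seeing the data.

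The comparison of injury with control asks which transcripts changed with spinal cord injury. The name-stable genes Ptprz1, Gpr37 and Gabbr2 had high counts in all 3 injury libraries and in control 3 and low counts in controls 1 and 2, and Slc13a1 the opposite. Ptprz1, a receptor phosphatase and proteoglycan of glia, averaged 1819 ± 94.8 CPM (counts scaled to a library total of 1000000; SD, n = 3) after injury and 595 ± 1018 CPM (n = 3) in control. The control libraries held 10.5, 3.82 and 1770 CPM of it. Slc13a1, a sodium and sulphate cotransporter, averaged 2.59 ± 1.82 CPM after injury and 781 ± 699 CPM in control, with 981, 1359 and 4.59 CPM in controls 1, 2 and 3. The log2 fold change was 1.76 (SE 1.94) for Ptprz1 with an adjusted p of 0.532, and -8.03 (SE 1.99) for Slc13a1 with an adjusted p of 0.118 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment).

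Of 12646 tested features, 0 were higher and 0 lower after injury at an adjusted p of 0.05 in edgeR's quasi-likelihood test. The smallest adjusted p was 0.118, and 3245 features had an unadjusted p under 0.05. In counts simulated with the spread of all 6 libraries, this test recovered 0% of genes changed 16-fold. So its 0 calls do not show that no feature changed. limma-voom also called 0. DESeq2 called 1503 features, 18 higher and 1485 lower, and limma-voom with sample quality weights called 7042, 3425 higher and 3617 lower. Without control 3 the edgeR test called 10231 of 15320 features, 4621 higher and 5610 lower, and without any other single library it called 0. Without controls 1 and 2 it called 939, an alternative chosen after seeing the data.

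The 5 features with the smallest unadjusted p in each direction did not pass. Among the 5 with higher values after injury, the feature named Cnfn had 12.4 ± 3.96 CPM after injury and 3.45 ± 1.46 CPM in control (n = 3 each; log2 fold change 2.02, SE 0.49, edgeR adjusted p 0.118). It lies on chromosome 7 from 25067045 to 25069149 in the files and falls on exons of Grik5, a kainate receptor subunit, in GRCm38. The other four were Gm11942, which is name-stable, D830036C21Rik (on exons of Dmwd), Gm16099 (Sppl2b) and D5Ertd579e (Man2b2), with log2 fold changes of 2.41, 1.64, 1.80 and 1.37. Among the 5 with lower values, the feature named Nipsnap1 (chromosome 11, 4823951 to 4844200 in the files) had 1.81 ± 0.824 CPM after injury and 19.0 ± 12.3 CPM in control, and falls on exons of Nf2. The feature named Atp1b3, on exons of Gm37195, had 3.76 ± 0.716 CPM after injury and 22.1 ± 9.21 CPM in control, and Gm48766, Gm28403 and Gm16353, which lie in introns, had log2 fold changes of -3.56, -2.51 and -3.59.

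Of 18 genes set in advance for this tissue and injury, 9 were tested by name, none passed and none is name-stable. The feature named Mbp, which has 2.80% of its exonic bases on exons of Mbp, averaged 9063 ± 432 CPM after injury and 2943 ± 5050 CPM in control (n = 3 each; log2 fold change 1.77, SE 2.08, edgeR adjusted p 0.555). The feature named Gfap falls on exons of Adam11 and averaged 105 ± 7.50 CPM after injury and 42.0 ± 44.1 CPM in control. The feature named Cd68 falls on exons of Efnb3 and averaged 396 ± 15.5 CPM after injury and 110 ± 188 CPM in control. These control means mix unlike libraries, with 15.1, 39.0 and 8774 CPM of Mbp in controls 1, 2 and 3. Without control 3 the log2 fold changes of the features named Mbp, Cd68 and Gfap were 8.97, 8.80 and 3.21 and passed, and without controls 1 and 2 they were 0.17, 0.40 and 0.31 and did not pass. The feature named Il1b falls on exons of Slc20a1 and averaged 123 ± 14.3 CPM after injury and 165 ± 129 CPM in control. The edgeR adjusted p was 0.255 for Gfap, 0.483 for Cd68, 0.711 for Il1b, 0.222 for Tmem119 (on exons of Ssh1), 0.148 for P2ry12 (in introns), 0.680 for Atf3 (on exons of Vash2) and 0.753 for Gap43 (in introns). Aif1, Snap25, Acan, Col2a1, T, Acta1, Hbb-bs, S100a8 and Ccl2 did not pass the count filter by name. The feature named Col2a1 falls on exons of Vdr and had 321 and 174 CPM in controls 1 and 2 and between 1.72 and 2.10 CPM in the other 4 libraries.

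Leaving out control 3 set controls 1 and 2 against the 3 injury libraries, and was planned as 1 of the leave-one-out fits. Among 518 name-stable genes tested in this way, 150 were higher and 173 lower in the injury libraries. In the fit over all features, with its own scaling and spread, 277 name-stable genes were higher and 99 lower, and 150 higher and 99 lower passed in both fits. With control 3 in, 0 of 461 passed and 86 had an unadjusted p under 0.05. The 12 genes with the largest rises were Frrs1l, Pou3f2, Clvs1, Gpr37, Necab1, Kcns2, Dync1i1, Gabbr2, Lingo2, Ptprz1, Nxph1 and Nkain3. Frrs1l, a protein of AMPA receptor complexes (chromosome 4, 56957173 to 56990391, the same in the files and in GRCm38), had 1 count over controls 1 and 2 together and 1168, 1328 and 1251 CPM in the injury libraries. Gpr37, an orphan receptor of oligodendrocytes, had 0.257 and 1.27 CPM in controls 1 and 2 and 1026, 1051 and 1031 CPM after injury (log2 fold change 9.78, SE 0.51, edgeR adjusted p 3.89e-04). Gabbr2, a subunit of the GABA-B receptor (chromosome 4, 46662305 to 46991873), had 4.88 and 0.255 CPM in those controls and 816, 751 and 756 CPM after injury (log2 fold change 7.51, SE 1.14, edgeR adjusted p 0.00448). Pou3f2, a transcription factor of neural cells, had 0 counts in controls 1 and 2 and was at least 576-fold higher in the injury libraries, taking 3 counts over the group as the floor. In control 3 these 4 genes stood at 1120, 954, 655 and 187 CPM, and none of the 12 passed between control 3 and the injury libraries (smallest adjusted p 0.160, for Gabbr2, in the edgeR fit over all features without controls 1 and 2).

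Among the 12 name-stable genes with the largest falls in this fit were Slc7a13, Acnat2, Tfec, Aqp3, Mmp7, Slc13a1, Atp6v0d2, Mmp3, Gata6os, Stra6l and Gata6. Slc13a1 (chromosome 6, 24088282 to 24168091) had 981 and 1359 CPM in controls 1 and 2 and 4.47, 2.46 and 0.838 CPM after injury (log2 fold change -9.35, SE 0.62, edgeR adjusted p 6.00e-04). Slc7a13, an amino acid transporter, had 1233 and 140 CPM in controls 1 and 2 and 0 counts in the injury libraries. Aqp3, a water and glycerol channel, had 35.2 and 37.0 CPM in those controls and 0 counts after injury, at least 97.9-fold lower. Atp6v0d2, a subunit of the proton pump, had 84.2 and 131 CPM in controls 1 and 2 and between 0.344 and 0.838 CPM after injury. Control 3 held 4.59 CPM of Slc13a1, 0.382 CPM of Atp6v0d2 and 0 counts of Slc7a13 and Aqp3. A count of 0 allows up to 0.369 CPM over the 3 injury libraries, for counting error only.

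**Figure D1:**
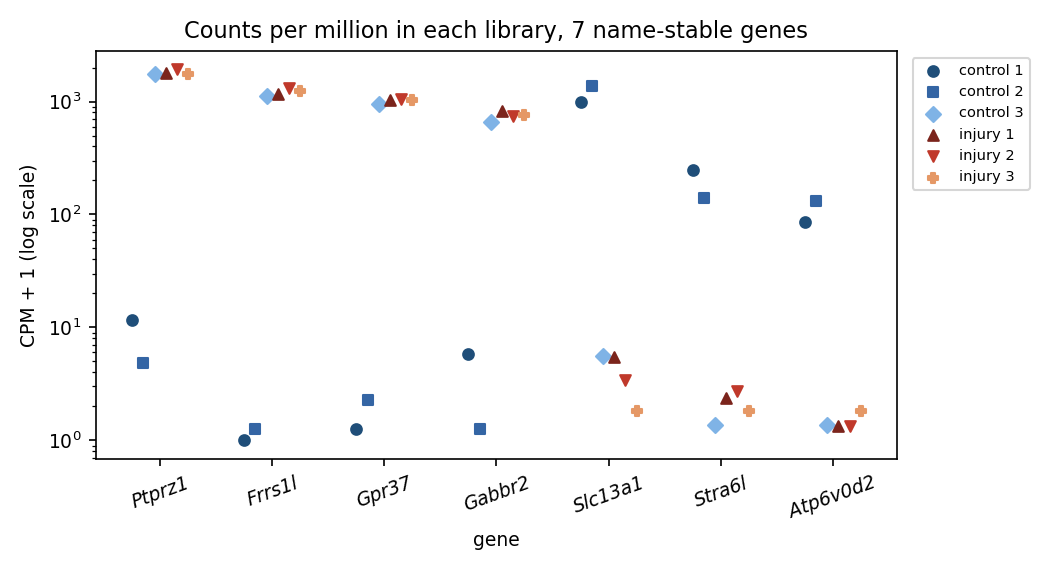
CPM plus 1, on a log scale, of 7 name-stable genes in each library, with 1 point per library and no error bars. Ptprz1, Frrs1l, Gpr37 and Gabbr2 lie at 655 CPM or above in control 3 and the injury libraries and at 10.5 CPM or below in controls 1 and 2, and Slc13a1, Stra6l and Atp6v0d2 lie at 84.2 CPM or above in controls 1 and 2 and at 4.59 CPM or below in the other 4.

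The same separation held over all features. On the 500 most variable tested features, the first principal component carried 98.0% of the variance, with controls 1 and 2 at -101 and -86.3, control 3 at 44.5, and injury 1, 2 and 3 at 46.2, 48.4 and 48.0. Across features, the log2 CPM of control 3 correlated with the injury libraries at Pearson r of 0.958 to 0.967 and with controls 1 and 2 at 0.405 and 0.394. Controls 1 and 2 correlated with each other at 0.834. These correlations are across features, which are not independent replicates.

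**Figure D2:**
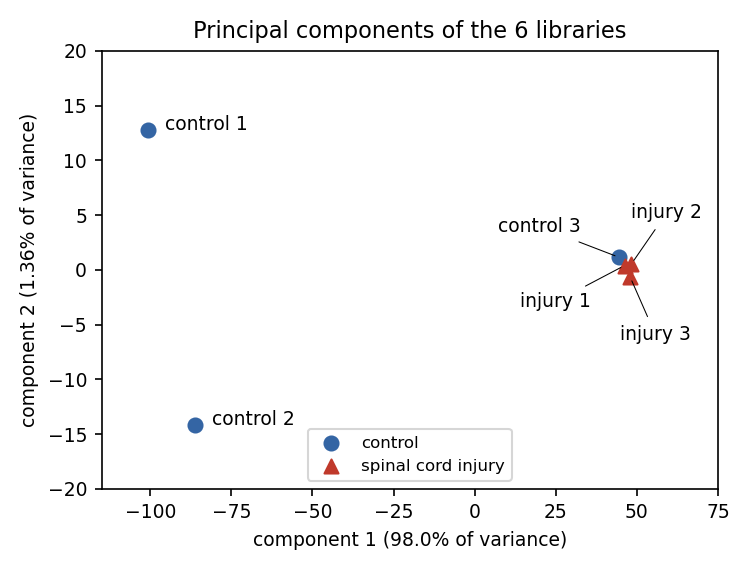
First and second principal components of log2 CPM over the 500 most variable tested features, with 1 point per library, circles for control and triangles for spinal cord injury. Control 3 lies at 44.5 on the first component beside the injury libraries at 46.2 to 48.4, and controls 1 and 2 lie at -101 and -86.3.

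Gene groups fixed before the data were examined were read by overlying gene, since 7 of their 212 members tested by name are name-stable. Synaptic and ion channel genes, myelin genes, and proteoglycans and inhibitors of axon growth were called higher in the injury libraries in this reading by camera with a preset correlation, but not with an estimated correlation and not without controls 1 and 2. Without control 3, all 10 tested synaptic and channel genes rose, over all genes tested and adjusted over the list alone. Scn1a, a sodium channel, had 0 and 0.255 CPM in controls 1 and 2, 853 CPM in control 3, and 789, 829 and 817 CPM in injury 1, 2 and 3. Gria2, an AMPA receptor subunit, had 0 counts in controls 1 and 2, 148 CPM in control 3, and 100.1, 120.1 and 81.3 CPM after injury. All 7 tested myelin genes rose over all genes and adjusted over the list alone, among them Cnp, an enzyme of myelin, from 12.3 and 41.3 CPM in controls 1 and 2 to 1269, 1225 and 1131 CPM, with 1034 CPM in control 3. Of 8 tested proteoglycans and growth inhibitors 7 rose, likewise over all genes and adjusted over the list alone. Among them Ncan, a proteoglycan of the nervous system, had 0 counts in controls 1 and 2, 54.3 CPM in control 3, and 79.8, 65.3 and 71.7 CPM after injury.

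These 3 lists were called by camera (two-sided, preset correlation of 0.01) with all 6 libraries, where none of their members passed singly, and without control 3. The adjusted p was 0.00155, 0.00512 and 0.00512 with all 6 and 6.94e-07, 5.25e-05 and 2.58e-04 without control 3, in the order synaptic, myelin, proteoglycan. With an estimated correlation the adjusted p was 0.789 for each of the 3 with all 6 libraries, and 0.230, 0.230 and 0.309 without control 3. Without controls 1 and 2 the preset test gave an adjusted p of 0.467, 0.164 and 0.170, and 0 of their members passed over all genes.

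Other groups, only some of them described here, held members that passed in the fit without control 3, with none of these lists called by camera. Of all 5456 genes tested in that fit 1535 rose and 1737 fell, so a few members passing is not particular to a list. All 4 tested monocyte and macrophage genes fell over all genes and adjusted over the list alone (camera adjusted p 0.213), among them Mrc1, a scavenging receptor of macrophages, from 10.3 and 92.8 CPM in controls 1 and 2 to between 0.688 and 3.35 CPM after injury, with 1.53 CPM in control 3. The fall of Ccr2, a chemokine receptor, rests on control 2 alone, with 5.39 and 208 CPM in controls 1 and 2 and 5.51, 1.76 and 3.77 CPM after injury. Of 6 tested genes of hypoxia and glycolysis 3 fell, over all genes and adjusted over the list alone, including Slc2a1, a glucose transporter, and Adm, a vasoactive peptide (camera adjusted p 0.213). Of 6 tested immediate early genes Junb, Ier2 and Btg2 fell and Arc rose, and adjusted over the list alone 5 fell and 1 rose (camera adjusted p 0.404). Of 3 tested genes of the reactive astrocyte list Cd44 and Osmr fell, by both counts, and Vim had 21.0 and 157 CPM in controls 1 and 2 and 436, 327 and 97.7 CPM after injury (camera adjusted p 0.424). Of 3 tested cartilage and disc genes Acan and Col11a2 rose, by both counts, and Acan stayed at 11.5 CPM or below in all 6 libraries (camera adjusted p 0.236). Of the genes named in this paragraph none passed between control 3 and the injury libraries, and Mrc1 and Ier2 did not pass the count filter there.

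By name, with all 6 libraries, camera called 0 of 37 lists with at least 3 tested members, and the smallest adjusted p was 0.138, for the synaptic and ion channel list. fry, which asks whether a list's genes move one way on balance, called 1 list, the regeneration associated genes, as lower (adjusted p 0.0174), where camera gave 0.893. None of its 6 tested members is name-stable, so the call cannot be read as one about the genes named. Adjusted over the list alone, 19 members in 14 lists were lower and 0 higher. None of the lower members is name-stable, and several, such as Syt1, Slc18a3 and Apoe, lie in introns. The monocyte list has 1 tested member, Arg1, so its p was not adjusted at all. These falls therefore cannot be read as falls of the genes named. Without control 3, camera called 2 lists by name, the synaptic and the myelin list, and without injury 1, 2 or 3 the synaptic list, all with the preset correlation. None of the 14 and 7 members tested by name with all 6 libraries is name-stable, though Gjc3 and Mbp lie partly on their own exons. The members tested in the other fits may differ. So these calls too cannot be read as about the genes named.

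Leaving out controls 1 and 2 set control 3 alone against the 3 injury libraries, so the lone control is assumed to vary like the injury libraries. Of 482 name-stable genes tested in the fit over all features, 6 were higher and 4 lower after injury. Fitted alone, the same genes gave 2 higher and 9 lower, but that fit pooled all spread between genes, so that its p-values ignore a gene's own spread and its genes are not named for it. 1 gene was higher in both fits and 4 were lower in both. Impdh1, an enzyme of guanine nucleotide synthesis, had 117 CPM in control 3 and 181, 171 and 213 CPM after injury (log2 fold change 0.81, SE 0.19, edgeR adjusted p 0.0127). Zcchc7, a zinc finger protein, had 351 CPM in control 3 and 212, 218 and 165 CPM after injury (log2 fold change -0.70, SE 0.16, edgeR adjusted p 0.0123). By overlying gene neither passed (adjusted p 0.117 and 0.0682).

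Over all 13857 features tested in this fit, 146 were higher and 793 lower after injury. Features in introns made up 19.9% of those tested and 60.0% of those called lower. Their share of all counts was 3.76% (95% Wilson interval 3.73% to 3.78%) in control 3, 2.03% (2.01% to 2.04%), 1.69% (1.68% to 1.71%) and 1.56% (1.55% to 1.58%) in injury 1, 2 and 3, and 7.12% (7.10% to 7.15%) and 11.01% (10.98% to 11.05%) in controls 1 and 2. By overlying gene, 0 of 5100 were higher and 28 lower, including Sema6d, a guidance cue for axons, at 37.1 CPM in control 3 and 9.98, 11.9 and 12.99 CPM after injury. The fibroblast and scar list was called higher (camera adjusted p 0.0202), with 0 of its 7 tested members passing, and the adjusted p was 0.866 with an estimated correlation. Its member Col1a1 had 13.4 CPM in control 3 and 15.5, 11.6 and 174 CPM in injury 1, 2 and 3.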

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

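The fits by overlying gene, on name-stable genes, and without controls 1 and 2 were chosen after seeing the data. The count of 0 features between injury and control held under RLE, upper quartile and total count scaling, both other filters, limma-voom and removal of the most abundant features. These alternatives keep the same unlike control libraries. With the spread of all 6 libraries, the main test recovered 0% of simulated genes changed 16-fold, so the repeated 0 does not show that no feature changed. Both stricter thresholds select from the 0 calls of the main fit and could only give 0. Relative to a median log2 fold change of -0.04 with TMM, total count scaling moved it to -0.30 and upper quartile scaling to -0.21. DESeq2 called 1503 (18 higher, 1485 lower) and limma-voom with sample quality weights 7042 (3425 higher, 3617 lower), and the cause was not tested. Leaving out each library gave 0 to 10231 calls (0 to 4621 higher, 0 to 5610 lower), the highest without control 3, where DESeq2 called 9820 and limma-voom 10141. Without controls 1 and 2 there were 939 (146 higher, 793 lower). Name-stable genes gave 323 (150 higher, 173 lower) without control 3 and 11 (2 higher, 9 lower) without controls 1 and 2, where that fit pooled all spread between genes. By overlying gene there were 3272 (1535 higher, 1737 lower) without control 3 and 28 (0 higher, 28 lower) without controls 1 and 2. Both readings gave 0 with all 6 libraries.

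Against 0 lists called by name, fry called 1 list by direction and 0 for change in either direction, the filter of 1 CPM in 3 samples 1 list, and leaving out each library 0 to 2 lists, the most without control 3. By overlying gene 3 lists were called with all 6 libraries, 3 without control 3 and 1 without controls 1 and 2. The first component carried 85.3% of the variance over all tested features and 97.8% with a prior count of 0.5, with control 3 on the injury side in both. With the replicate number as a block, edgeR called 0 features and 0 lists. Deviations from the group means correlated at 0.065, -0.138 and 0.059 for numbers 1, 2 and 3. The control mean mixes unlike libraries, and the fit without a block also called 0 features. So neither result can tell whether the numbers pair the libraries.

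Of 19 features tested under the names of genes that the rule takes, 15 passed without control 3, 10 in DESeq2 and 13 with sample quality weights. None passed under the other alternatives run for single genes, the fit without controls 1 and 2 aside. Only Gm11942 of the 19 is name-stable, so for the others these results are not about the genes named. The log2 fold change of the feature named Il1b turned from -0.41 to 0.077 in limma-voom, 0.65 with quality weights and 0.10 with the replicate block, and ranged from -0.91 to 0.58 when each library was left out, with 0.58 without control 1. That of the feature named Atf3 (on exons of Vash2), 0.32, ranged from -0.048 without control 1 to 0.86 without control 3. It was -0.12 without controls 1 and 2, where that of the feature named Gap43 (in introns) turned from 0.75 to -0.90. No reversed value passed the threshold. The cause was not tested. The limma tests planned for normalized values, which need a pseudocount, were not run, since counts were used. Correlations of log2 CPM and the 4-fold comparisons of tissue markers added 1 CPM to each value. With depths of 2385703 to 3921627 counts, a gene with 0 counts over controls 1 and 2 lay at or below 0.384 CPM.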

Other observations

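The genes of the first 2 paragraphs were picked after their values were seen, as were the split of densities by gene type and the tests of excluded reads, of treatment, of intron features and of carry-over. By overlying gene, 4 genes were picked for their spread among the injury libraries, with no test between them. Vim, an intermediate filament of reactive astrocytes, stood at 436, 327 and 97.7 CPM in injury 1, 2 and 3 and at 132 CPM in control 3. C4b, a complement component, stood at 362, 210 and 74.6 CPM, against 127 CPM in control 3. Clec7a, a receptor of activated microglia, stood at 48.2, 36.9 and 6.29 CPM, against 13.001 CPM. C1qc, a complement subunit made by microglia, stood at 106, 69.9 and 34.8 CPM, against 43.2 CPM. For these 4 genes injury 3 lay below control 3, and none was called between control 3 and the injury libraries (edgeR adjusted p of 0.356, 0.523, 0.431 and 0.421, in the order named).

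Injury 3 also held more counts of 3 other genes picked in this way. Myh4, a fast myosin heavy chain, stood at 78.8 CPM there, at 1.03 and 0.351 CPM in injury 1 and 2, and at 12.6 CPM in control 3. Atp2a1, the calcium pump of fast muscle, stood at 49.0 CPM in injury 3 and at 3.06 CPM or below in the other libraries. Prx, a protein of Schwann cells, stood at 114 CPM in injury 3 and at 18.6 CPM or below elsewhere, while Cdh19, another gene of Schwann cells, stood at 39.2, 51.6 and 60.8 CPM in injury 1, 2 and 3 and at 47.0 CPM in control 3. Hbb-bs, an adult beta globin, stood at 394, 5.27 and 83.8 CPM in injury 1, 2 and 3 and at 347 CPM in control 3.

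Gene names and counted positions did not match. Reads placed on GRCm38 and counted over features from another build may account for it: 77 ribosomal protein features off their own GRCm38 exons had a median of 1.60 CPM, and the 2 on their own exons 364 CPM. Features on exons of other genes held a median of 50.8 counts per kb, features in introns 15.2 and features outside genes 0, but name-stable features only 1.73, and 269 for those that are protein coding and not on Y, with the density on such exons above that off exons on 20 of 20 chromosomes, Y left out. The leaving out of multi-mapping and overlapping reads is argued against as the cause, since 29 neuron and myelin features off their own exons reached a median of at most 2.29 CPM in control 3 and the injury libraries. No biological explanation was tested for this pattern.

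Controls 1 and 2 stood apart from control 3 and the injury libraries. A difference from treatment alone is argued against by the pattern itself, unless the label of control 3 is wrong. Control 3 correlated with each injury library at 0.958 or more and with either other control at 0.405 or less. These correlations restate the pattern and are no separate test. Disc RNA is argued against too, but only for the markers that could be read. Of 27 cartilage, disc and notochord markers 11 had an overlying feature, and Col2a1 and T had none. Of the 11, 18.2%, Krt8 and Car12, were at least 4 times higher in both controls than in each other library. Kidney RNA stays open as a hypothesis, raised by name-stable genes such as Slc13a1 that were left out of its test: 57.1% of 7 kidney markers were, among them Slc34a1, Lrp2 and Kl, against 50% of 4 liver, 42.9% of 7 intestine and 0% of 3 lung markers, too few to set kidney apart from another epithelial organ. Slc34a1 stood at 828 and 122 CPM in these controls with 0 counts in the other 4 libraries, while Calb1, which neurons also express, stood at 216 CPM or above in those 4.

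Control 3 differed from the injury libraries, with most calls lower after injury in the fit without controls 1 and 2. There the median log2 fold change was -1.11 for features in introns and 0.18 for name-stable genes. No like baseline comes from setting injury 1, 2 or 3 alone, since control 3 then adds to the spread of the other group. More unspliced RNA or genomic DNA in control 3 may account for most of the lower calls: 60.0% of them were features in introns, 3.01 times the share of tested features and barely past the bound of 3, of which 17.2% were called lower, against 0.830% of name-stable genes. Carry-over from controls 1 and 2 is argued against, since 50 features high in both and under 5 CPM in the injury libraries had a median excess in control 3 of 0% of their level. A tissue response to injury stays open: 0 of the response lists were higher, but only 3 of 6 had enough tested members (smallest adjusted p 0.258) and there is 1 control library.

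The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The labelled split called 0 genes and the highest of the others 0, so all 10 splits gave as many. At an unadjusted p under 0.05 the labelled split had 3245 features and the highest other 1779, and the labelled split called 0 lists, where the highest other called 2 and all 10 gave as many. All 4 Y-linked name-stable genes looked up, Ddx3y, Uty, Kdm5d and Eif2s3y, had counts in all 6 libraries. In the deposited columns named FPKM every value above 0 matched, within a relative tolerance of 1e-06, a scaled count divided by feature length and library total, and by that total a second time. The second division alone raises the mean log2 value in injury by 0.339 relative to control.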
